A study of Mus musculus with 10 samples.

How the data were processed

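RNA from splenic CD4+ T cells of 10 female mice aged 6 months was measured on 1-colour oligonucleotide arrays, with 5 C57BL/6 (B6) mice and 5 B6.Sle1c2 mice. Per the labels, the cells were enriched from spleen with magnetic beads that removed other cells (negative selection), total RNA was extracted with kits, and biotin-labelled cDNA was made with an amplification kit. The design text of the series gives 5 mice from each strain, so each of the 10 arrays was taken as 1 animal, and the p-values describe variation between animals on that reading. The deposited values were intensity values on a linear scale, 1 per probe set, for 45101 probe sets, of which 64 were manufacturer's controls. How the authors summarised the probes, corrected the background and normalised the arrays was not given in the sources used here. The replicate numbers were those of the labels, and 0 columns were left unused.

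Values below 1 were set to 1 and log2 was taken. The array medians lay within 0.169 of each other on the log2 scale, under the limit of 0.2 set beforehand, so no further normalisation was applied. Control probe sets were removed, and the 31526 of 45037 probe sets whose mean log2 value reached the 30th percentile (3.09, an intensity of 8.52) were kept. Among the probe sets, 34958 had 1 gene symbol, 932 had several and 9160 had none in the annotation used, and only those with 1 symbol were named. Gene symbols and gene order came from a RefSeq gene table of assembly GRCm38.p6, in which 34754 of those probe sets were matched by gene identifier. Each gene was represented by its kept probe set of highest mean over all arrays, which gave 13968 genes.

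Strains were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the data.table package (version 1.17.8), and p-values were adjusted by the Benjamini-Hochberg method over probe sets or over genes, with a threshold of 0.05. Differences are B6.Sle1c2 minus B6 on the log2 scale, ± SE, and intervals are 95% intervals from the moderated fit (9.92 degrees of freedom). A set of 35 gene lists, fixed before the data were examined, was tested with camera (preset correlation of 0.01), which compares a list with the other genes, and adjusted over the lists. Of the 657 gene entries in these lists, 73 were not matched and are not analysed here. Called genes near Esrrg were counted among up to 50 tested genes on either side and compared with all other genes by a two-sided Fisher's exact test. Single values with 5 mice per strain were compared by two-sided exact permutation tests, whose smallest possible p is 0.00794. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

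The genes named in the text followed a rule set beforehand. It took the 12 called genes with the largest difference in each direction, leaving out immunoglobulin and T cell receptor segments and predicted genes without a functional name. It also took every gene of the region list, and of each other list up to 4 called members, or otherwise the 2 of smallest p. Some genes that it took but that were not called are left unnamed in the text. Other genes are named as chosen after their values were seen.

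A background reference was chosen after the data were seen: the 27 probe sets for bacterial control transcripts had a median intensity of 4.81, a 95th percentile of 11.6 and a maximum of 30.3. Where 1 strain's mean lay below that 95th percentile, the difference is given as a bound, with the dim strain's values raised to it. The number of arrays limits the precision. In 5 simulated data sets with the spread of the real arrays for this comparison, with 200 of 31526 probe sets changed, limma recovered 30.7% of changes of 0.5, 62.1% of changes of 1 and 90.6% of changes of 2 on the log2 scale, and 6.44% of calls were false. The simulated probe sets varied independently, unlike those on real arrays, so that share of false calls need not hold here. In a simulation on 13968 genes, camera recovered a list shifted by 0.3 and called 0 of 30 lists that shared no gene with it. The genes of that simulation also varied independently, unlike real genes.

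Alternatives set beforehand covered the filter, quantile normalisation, an offset of 32, eBayes with trend and robust fitting, array weights, the replicate number as a block, the mean of a gene's probe sets, other list tests, other windows and each array left out. Alternatives without both arrays of low 5' signal, with the 5' to 3' control ratio or the level of erythroid markers as a covariate, and with a limit on level were added after the data were seen. The direction of a list across alternatives was read from its median difference, a choice made after a first reading from the direction of the camera test.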

Results

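CD4+ T cells from spleen were profiled in B6 mice and in B6.Sle1c2 mice, a congenic strain that carries a lupus-associated interval of distal chromosome 1, around the nuclear receptor gene Esrrg, on the B6 background. The design asked which genes these cells expressed differently in the 2 strains. Each strain had 5 female mice and 5 arrays. Median intensity lay between 31.2 and 35.1 on the 10 arrays, and 65.0% to 65.7% of probe sets exceeded the background reference. No pair of arrays held identical values: the SD of the log2 differences between arrays, over probe sets of mean log2 of at least 8, ran from 0.162 to 0.486. RNA quality differed between arrays within each strain. The ratio of 5' to 3' signal of the Gapdh control was 3.62% in B6 replicate 4 and 4.04% in B6.Sle1c2 replicate 4, against 14.2% to 25.95% in the other 8 arrays. For the beta-actin control it was 9.42% and 11.6%, against 25.5% to 34.6%.

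Genes of cytokines and T cell effector states were among those that differed between the strains. Il17a, which encodes the cytokine interleukin 17A, rose by 2.65 ± 0.31 on the log2 scale in B6.Sle1c2 cells (6.28-fold, 95% interval 3.90 to 10.1, n = 5 per strain, limma adjusted p = 0.00451). Ppp2r2c, a regulatory subunit of protein phosphatase 2A, had the largest rise of a named gene, at least 6.85-fold, with a B6 mean below the background reference (adjusted p = 0.00626). Zbtb32, a transcriptional repressor of lymphocytes, rose by 1.88 ± 0.24, and Fcgr4, an activating Fc receptor of myeloid cells, rose by 1.90 ± 0.38. Gja1, the gap junction protein connexin 43, fell by 2.01 on the log2 scale (SE 0.19, adjusted p = 0.00348), and Ephx2, soluble epoxide hydrolase, fell by 1.85 (SE 0.26).

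The other large rises were in Esm1 (2.75 ± 0.55), Pdzrn3 (2.43 ± 0.53), Kcnc2 (2.20 ± 0.36), Smpdl3b (1.93 ± 0.24) and Car5b (1.86 ± 0.19), of which Esm1 and Pdzrn3 lost their calls in 11 and 12 of 21 alternatives. Cyp17a1, Epha3 and Lmo1 rose at least 3.93-fold, 2.31-fold and 1.92-fold from B6 means below the background reference. The other large falls were in Pgap4 (-2.18 ± 0.22), Acsl6 (-2.12 ± 0.26), Ccdc68 (-1.86 ± 0.24), Gdf3 (-1.85 ± 0.26), Zg16 (-1.83 ± 0.20), Jcad (-1.77 ± 0.20), Mc1r (-1.65 ± 0.21) and Pklr (-1.65 ± 0.28). The large fall in Pklr was seen in its brighter probe set only. Its other kept probe set, of mean log2 6.2, had a difference of -0.11 ± 0.21. The dimmest of the 6 kept Gja1 probe sets, of mean log2 4.35, had a difference of -0.03 ± 0.26. The rest of them ranged from -1.933 to -2.015. The other kept probe set of Gdf3 had a difference of -0.72 ± 0.27. Nkx1-2 and Stab1 were at least 2.42-fold and 2.36-fold lower, and Stab1 lost its call in 10 of 20 alternatives. In each of these 24 genes the 5 values of one strain did not overlap the 5 of the other. Adjusted p ranged from 0.00348 (Gja1, Pgap4, Car5b) to 0.0429 (Pdzrn3).

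A few called genes outside the naming rule were chosen after their values were seen. The transcript 5830416I19Rik had the smallest p of all genes and was at least 5.12-fold lower in B6.Sle1c2 cells (adjusted p = 2.957e-08), with a log2 mean of 5.90 ± 0.13 (SD, n = 5) in B6 and 2.44 ± 0.10 in B6.Sle1c2, the latter below the background reference. A strain variant under its probes, which would lower the signal without a change in expression, could not be checked here. Ighg3, an immunoglobulin heavy chain constant gene of antibody-secreting B cells, fell by 2.84 on the log2 scale (SE 0.48, adjusted p = 0.0156).

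In all, limma called 524 of 31526 probe sets, 281 higher and 243 lower, and 378 of 13968 genes, 200 higher and 178 lower. With quantile normalisation the split over probe sets was 322 higher and 180 lower, while without both arrays of low 5' signal it was 212 higher and 267 lower. Of the called genes, 63 rose and 71 fell at least 2-fold, and the strains' values did not overlap in 357 of them. Over all genes 5.65% had no overlap, where chance gives 0.794%. The count of genes ran from 159 to 517 when 1 array was left out, was 335 without both arrays of low 5' signal, and was 191 with the level of erythroid markers as a covariate. The first principal component held 29.1% of the variance and did not separate the strains (exact permutation p = 0.119, n = 5 per strain), and the second held 22.3% (exact permutation p = 0.0238). Over the 1000 probe sets of largest variance, the mean score of the first component differed between strains (exact permutation p = 0.0238). The scores of the strains still overlapped there, since full separation would give the smallest possible p of that test, 0.00794.

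Genes of regulatory T cells rose as a list in B6.Sle1c2 cells with the preset correlation (camera adjusted p = 5.678e-12; adjusted p = 0.302 with an estimated correlation). Of 19 members measured, 18 had a higher mean, the median difference was 0.44, and 4 passed over all genes: Il10, an anti-inflammatory cytokine (1.62 ± 0.21, adjusted p = 0.00547), Itgae, the integrin CD103 (0.99 ± 0.11), Prdm1, the transcription factor Blimp-1 (0.81 ± 0.14), and Entpd1, the ectonucleotidase CD39 (0.76 ± 0.17, a call lost in 13 of 21 alternatives). Adjusted over the list alone, 13 members passed. Foxp3, the lineage factor of regulatory T cells and a gene chosen after its values were seen, was among these 13, with a difference of 0.41 ± 0.11 and an adjusted p of 0.0875 over all genes.

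Genes of follicular helper T cells, which help B cells in germinal centres, also rose as a list, with 17 of 18 members higher and a median difference of 0.44 (camera adjusted p = 5.921e-08; adjusted p = 0.523 with an estimated correlation). Over all genes 0 members passed in limma, and 11 passed adjusted over the list alone. Slamf6 and Cd200 had the smallest p-values, with differences of 0.52 ± 0.12 and 0.48 ± 0.12, and passed over all genes in 9 and 7 of 21 alternatives. The mean level of the list overlapped between strains: B6 replicates 1 and 4 stood at 10.94 and 10.90, near B6.Sle1c2 replicate 5 at 10.93, while B6 replicates 3 and 5 were far lower at 10.09 and 9.84. Without either of those 2 the list still passed (medians 0.38 and 0.34). T cell activation genes rose with a median of 0.32 over 22 members, 18 of them higher (camera adjusted p = 1.174e-05; adjusted p = 0.302 with an estimated correlation). Some activation genes are also members of the regulatory or follicular helper lists, so the shifts of these lists are not independent of each other. Lag3, an inhibitory receptor, passed over all genes (1.27 ± 0.25, a call lost in 10 of 21 alternatives), and 8 members of the activation list passed adjusted over the list alone.

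Th1 and cytotoxic genes rose, with 17 of 21 members higher and a median of 0.15 (camera adjusted p = 7.391e-05; adjusted p = 0.523 with an estimated correlation). That median was 0.092 without both arrays of low 5' signal and 0.080 without B6 replicate 4, and 0.22, 0.23 and 0.22 without B6 replicate 2 and B6.Sle1c2 replicates 1 and 4. Gzmk, a granzyme (1.61 ± 0.24), Eomes, a T-box factor (0.54 ± 0.07), Ifng (0.42 ± 0.08) and the chemokine gene Ccl4 (1.00 ± 0.21) passed over all genes, and 8 members passed adjusted over the list alone. Ifng and Ccl4 lost their calls in 8 and 9 of 21 alternatives. All 6 measured Th17 genes were higher, with a median of 0.21, and 2 passed both ways, Il17a and Ahr (0.48 ± 0.10), of which Ahr lost its call in 13 of 21 alternatives. That list had a camera adjusted p of 0.000125 and an adjusted p = 0.0890 with an estimated correlation. Type I interferon response genes rose, 22 of 26 higher, median 0.16 (camera adjusted p = 7.391e-05; adjusted p = 0.528 with an estimated correlation). Oas1a passed over all genes (0.58 ± 0.11, a call lost in 11 of 21 alternatives), and 5 passed adjusted over the list alone. Without B6 replicate 4 the interferon median was 0.097, and without B6 replicate 2 the Th17 median was 0.32.

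Smaller shifts were seen in 4 further lists of T cell and Sle1 genes. Early response genes rose with a median of 0.07 (20 of 25 members higher, camera adjusted p = 0.00347; adjusted p = 0.528 with an estimated correlation), Ier3 passing at 0.74 ± 0.11 and being the 1 member that passed adjusted over the list alone. T cell receptor signalling genes rose with a median of 0.07 (17 of 22 members higher, camera adjusted p = 0.0124, and adjusted p = 0.626 with an estimated correlation). Ubash3a and Cd28 had differences of 0.29 ± 0.07 and 0.16 ± 0.07, of which Ubash3a alone passed adjusted over the list alone. Its other probe set went the other way (-0.18 ± 0.21), and with the mean of its probe sets the Ubash3a difference was 0.056. Naive and resting genes fell, 16 of 17 lower, median -0.06 (camera adjusted p = 0.0132; adjusted p = 0.626 with an estimated correlation), and the homing receptor Ccr9 passed at -0.77 ± 0.12, the 1 member to do so either way. Other genes of the Sle1 locus had a median of 0.05 over 19 members (camera adjusted p = 0.0383; adjusted p = 0.528 with an estimated correlation), with Slamf1 (0.45 ± 0.08) and Ifi204 (1.54 ± 0.29) passing over all genes, and 3 members passing adjusted over the list alone, Slamf6 included. The shift of naive genes and that of the Sle1 genes did not pass without both arrays of low 5' signal (adjusted p = 0.113 and 0.0715). Naive genes also lost their shift without B6 replicate 3 or B6.Sle1c2 replicate 4 (adjusted p = 0.0912 and 0.0980). T cell receptor signalling lost it without B6 replicate 4 (0.0503) or with the mean of a gene's probe sets (0.0659). Without B6 replicate 4 the medians of early response and signalling genes were 0.023 and 0.027. The Sle1 genes lost their shift with that mean (0.0779) and without B6 replicate 1 or 4 or B6.Sle1c2 replicate 2 or 3 (0.0603, 0.0890, 0.0606 and 0.0573), and their median ran from 0.021 without B6 replicate 4 to 0.13 without B6 replicate 2. The naive median was -0.17 with the mean of a gene's probe sets, and -0.10 and -0.093 without B6 replicate 4 and B6.Sle1c2 replicate 2.

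**Figure D1:**
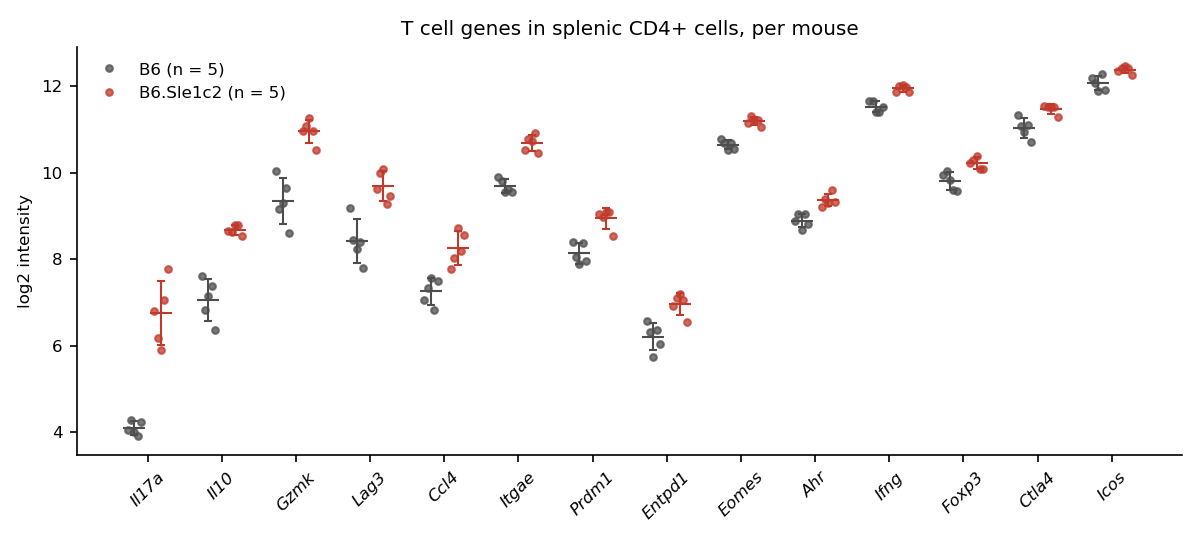
Log2 intensity of 14 T cell genes in each mouse, B6 in grey and B6.Sle1c2 in red, with bars for the mean ± SD of 5 mice. Il17a ran from a B6 mean of 4.09 to a B6.Sle1c2 mean of 6.74, while Foxp3, Ctla4 and Icos, chosen after their values were seen, did not pass over all genes.

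Transcripts of other cell types were present as well. Monocyte and macrophage markers were higher in B6.Sle1c2 cells, 17 of 18 members, with a median of 0.47 (camera adjusted p = 7.391e-05; adjusted p = 0.528 with an estimated correlation), and Cybb, a subunit of the phagocyte oxidase, passed at 0.77 ± 0.16 (a call lost in 11 of 21 alternatives). Adjusted over the list alone 2 members passed, and the median was 0.29 without B6 replicate 4. Their mean level per array was 7.72 ± 0.54 (SD, n = 5) in B6 and 8.23 ± 0.18 in B6.Sle1c2 (exact permutation p = 0.0714, adjusted 0.444). Across the 10 arrays this level rose with that of the regulatory T cell list (Pearson r = 0.685, permutation p = 0.023; Spearman rho = 0.770, permutation p = 0.013; adjusted over 3 relations 0.034 and 0.020; r = 0.674 without the 2 arrays farthest from the median, and 0.462 after the strain means were removed).

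Cell cycle genes were lower in B6.Sle1c2 cells in all 29 measured members, with a median of -0.33 and 0 members passing in limma, over all genes or adjusted over the list alone (camera adjusted p = 0.000166; adjusted p = 0.626 with an estimated correlation). Mcm2 and Mcm3, parts of the replicative helicase, had differences of -0.25 and -0.16. Erythroid markers were lower as well, in all 12 measured members, with a median of -0.47 (camera adjusted p = 0.00556; adjusted p = 0.626 with an estimated correlation), and Car1, a carbonic anhydrase of red cells, passed at -1.03 ± 0.19, the 1 member to do so either way. Without B6.Sle1c2 replicate 2 the erythroid list did not pass (median -0.23, adjusted p = 0.0606). Without both arrays of low 5' signal the cell cycle and erythroid medians were -0.58 and -0.80. The mean erythroid level was high in both strains, 11.4 ± 0.51 in B6 and 10.9 ± 0.59 in B6.Sle1c2 (SD, n = 5 each, exact permutation p = 0.206, adjusted 0.540). Across the 10 arrays the erythroid and cell cycle levels rose together (Pearson r = 0.950, permutation p = 4e-05; Spearman rho = 0.952, permutation p = 1e-04; adjusted over 3 relations 0.00012 and 3e-04; r = 0.957 without the 2 arrays farthest from the median, and 0.941 after the strain means were removed). Over all arrays the erythroid level did not follow the macrophage level (Pearson r = 0.249, permutation p = 0.50; Spearman rho = 0.273, permutation p = 0.45; adjusted 0.50 and 0.45; r = 0.180 without the 2 farthest arrays), though r was 0.699 after the strain means were removed. These 3 relations were chosen after the data were seen.

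Platelet markers fell, 9 of 10 lower, median -0.49 (camera adjusted p = 0.0342; adjusted p = 0.528 with an estimated correlation), with Itgb3 passing at -0.73 ± 0.16 (a call lost in 10 of 21 alternatives), the 1 member to do so either way. The list did not pass with the mean of a gene's probe sets (adjusted p = 0.0615) or without B6 replicate 2 or 3 or B6.Sle1c2 replicate 1 or 2 (0.0619, 0.0588, 0.0534 and 0.0859), with a median of -0.32 without B6 replicate 3. The lists for B cells (median -0.19), plasma cells (0.16), neutrophils (0.80), dendritic cells (-0.20), NK cells (-0.17), CD8 T cells (0.06), gamma-delta and innate-like T cells (0.31), mast cells and basophils (0.09), and stroma and endothelium (0.06) did not pass (camera adjusted p = 0.171, 0.0736, 0.191, 0.0799, 0.181, 0.463, 0.251, 0.908 and 0.463). Adjusted over each list alone, the members that passed numbered 0, 2, 1 (lower), 1 (lower), 5 (2 higher, 3 lower), 1, 5 (3 higher, 2 lower), 0 and 0. For mast cells the test pointed down while the median lay above 0. Within these lists Mmp9 (-1.003 ± 0.20) and Zbtb16, the factor PLZF of innate-like T cells (-0.84 ± 0.16, a call lost in 13 of 21 alternatives), fell and Cd163l1 (1.00 ± 0.17) rose. Of the B cell genes, Cr2 and Cd22 had differences of -1.56 ± 0.52 and 0.41 ± 0.13 and did not pass. Without both arrays of low 5' signal the B cell, plasma cell and dendritic cell lists passed, with medians of -0.33, 0.28 and -0.36 (adjusted p = 0.00203, 0.0156 and 0.0125). Without B6 replicate 4 alone the B cell and dendritic cell medians were -0.38 and -0.39 (adjusted p = 0.000666 and 0.00642), and without B6.Sle1c2 replicate 4 the plasma cell median was 0.33 (adjusted p = 0.0107). The plasma cell list also passed without B6 replicate 1 or 2 (medians 0.24 each, adjusted p = 0.0235 and 0.0483), and the dendritic cell list without B6.Sle1c2 replicate 2 (-0.31, adjusted p = 0.0467). The neutrophil list passed without B6 replicate 2, whose neutrophil level stood apart (median 1.07, adjusted p = 0.00488), while without both arrays of low 5' signal its median was 0.25. Neutrophil and NK cell lists also passed with the replicate block (0.0426 each).

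**Figure D2:**
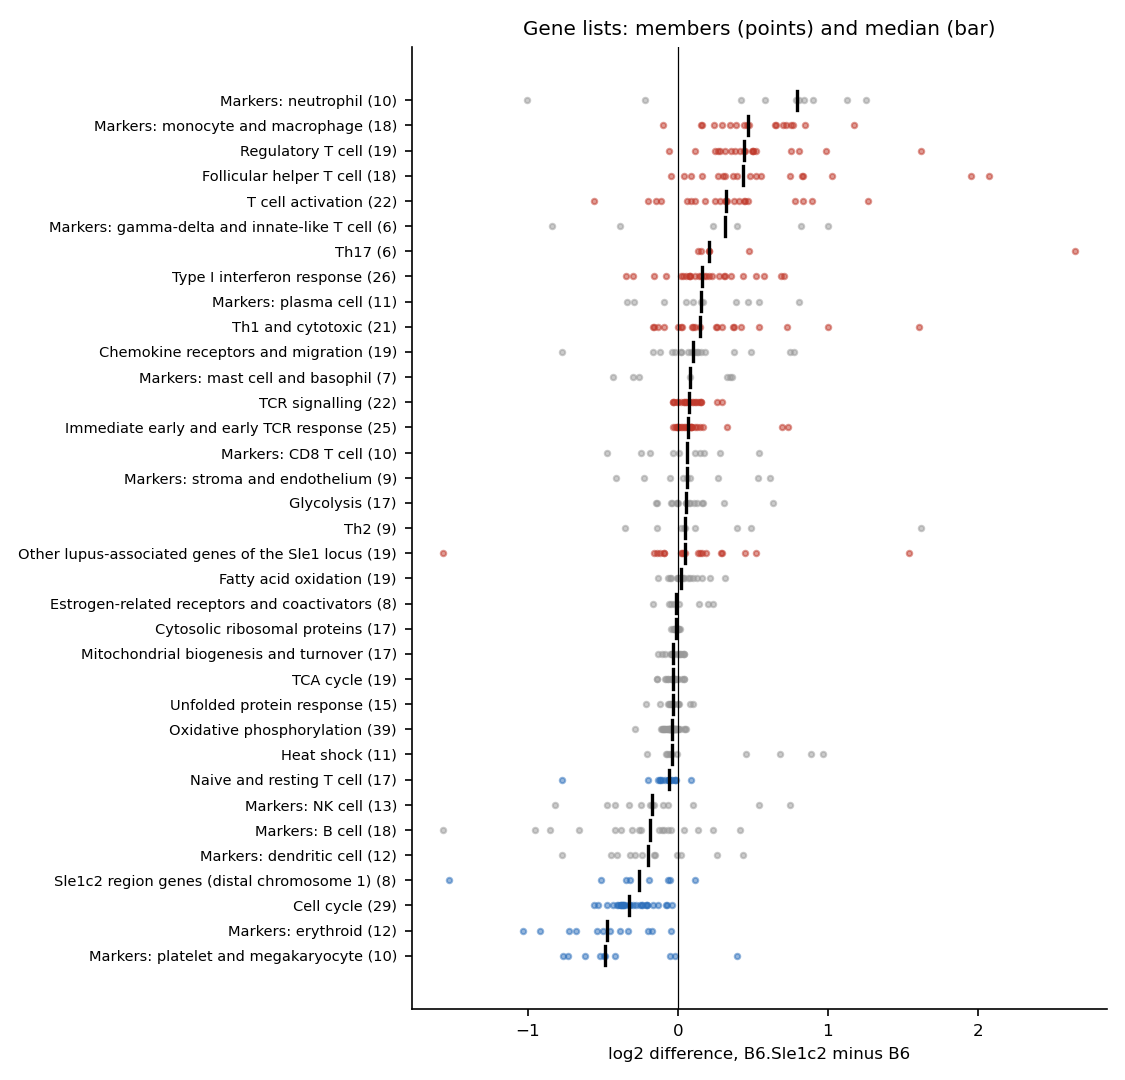
Log2 differences (B6.Sle1c2 minus B6) of the measured members of 35 gene lists, 1 point per gene, with a bar at each median and the number of members in brackets. Lists that passed with the preset correlation are red (10 higher) or blue (5 lower), and the others are grey.

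Genes of energy metabolism, the pathways that estrogen-related receptors regulate in other tissues, did not shift as lists with all arrays. Medians were -0.04 for 39 oxidative phosphorylation genes, -0.03 for 19 genes of the TCA cycle, 0.02 for 19 of fatty acid oxidation, 0.05 for 17 of glycolysis, -0.03 for 17 of mitochondrial biogenesis and turnover, and -0.01 for 8 estrogen-related receptors and coactivators (camera adjusted p = 0.180, 0.206, 0.191, 0.0846, 0.430 and 0.652). Slc16a3, a lactate transporter (0.64 ± 0.16), Cpt1a, of fatty acid import (0.32 ± 0.08), and Ncoa1, a coactivator (0.23 ± 0.07), did not pass over all genes. In 5, 7 and 4 of 21 alternatives, respectively, these 3 genes did pass. With all arrays Slc16a3 and Cpt1a passed adjusted over their own list alone, as did 0 other members of these 6 lists. Oxidative phosphorylation passed without B6 replicate 4, where its median was -0.12 (adjusted p = 0.000572), without both arrays of low 5' signal (-0.07, adjusted p = 0.00522) and with the replicate block (0.0442). Without B6.Sle1c2 replicate 4 its median was 0.0082 (adjusted p = 0.912), while glycolysis passed (0.10, adjusted p = 0.0290). The Th2, chemokine receptor, heat shock, unfolded protein response and ribosomal protein lists had medians of 0.05, 0.10, -0.04, -0.03 and -0.01 and did not pass (camera adjusted p = 0.0642, 0.0504, 0.430, 0.430 and 0.682). Adjusted over each list alone, 2, 3, 2, 0 and 0 members passed. Without both arrays of low 5' signal the Th2 and chemokine receptor lists passed (adjusted p = 0.0311 and 0.0283), as both did with the mean of a gene's probe sets (0.0479 and 0.0217) and without B6 replicate 2 (0.0310 each) or B6.Sle1c2 replicate 4 (0.0290 and 0.0258). The chemokine receptor list also passed with quantile normalisation (0.0420) and without B6.Sle1c2 replicate 3 (0.0456). Within these 5 lists Il10, Itgb1 (0.77 ± 0.12), Bag3 (0.68 ± 0.10) and Hspb1 (0.97 ± 0.20, a call lost in 12 of 21 alternatives) rose and Ccr9 fell. The heat shock and estrogen-related receptor lists had means of 0.23 and 0.04 and a test that pointed up, against medians below 0.

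The bounds of the congenic interval were not given in the sources used here, so the genes tested for it were a list of neighbours of Esrrg, and which of them lie inside the interval is not known here. Of the 25 probe sets of the 10 measured genes, 1 passed, of Ptpn14, a protein tyrosine phosphatase. This brightest probe set fell by 1.52 on the log2 scale (SE 0.22, n = 5 per strain, limma adjusted p = 0.0012 adjusted over the list alone; exact permutation p = 0.00794, the smallest the design allows). The other 2 Ptpn14 probe sets had differences of -0.52 and -0.34, with unadjusted limma p-values of 0.043 and 0.1003. Smyd2, a lysine methyltransferase, had a difference of -0.35 ± 0.10 and no overlap between strains, and did not pass among the 25 probe sets (adjusted p = 0.0726 over the list alone). It passed with quantile normalisation, the offset, trend and robust fitting, array weights, or B6 replicate 4 left out. Esrrg was near background: its 3 probe sets read between 1 and 26.7, 1 of them above the background reference on 4 of 10 arrays and the others on 0, with differences of 1.501 ± 0.68, -0.39 ± 0.28 and -0.09 ± 0.58 (adjusted p = 0.267, 0.550 and 0.941 over the list alone). The brightest probe sets of Lyplal1, Tgfb2, Rrp15, Spata17, Gpatch2, Cenpf and Prox1 had differences of -0.19, -0.32, -0.06, 0.18, 0.12, -0.51 and -0.05, and did not pass.

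The neighbours of Esrrg fell as a list, with 7 of 8 members lower and a median of -0.25 (camera adjusted p = 0.0395; adjusted p = 0.473 with an estimated correlation), and this did not pass without both arrays of low 5' signal (adjusted p = 0.0969), with the replicate block (0.0714), or without B6 replicate 1 or 4 or B6.Sle1c2 replicate 1, 2 or 5 (0.0508, 0.144, 0.0522, 0.109 and 0.0615). With 1 probe set per gene, 2 members passed adjusted over the list alone, Ptpn14 and Smyd2. Called genes were not concentrated around Esrrg. Among the 50 tested genes before Esrrg and the 38 that follow it up to the chromosome's end, 2 of 88 were called (2.27%), Lefty1 and Ptpn14, against 376 of 13880 elsewhere (2.71%; odds ratio 0.835, Fisher's exact p = 1). Lefty1 was named after its value was seen.

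**Figure D3:**
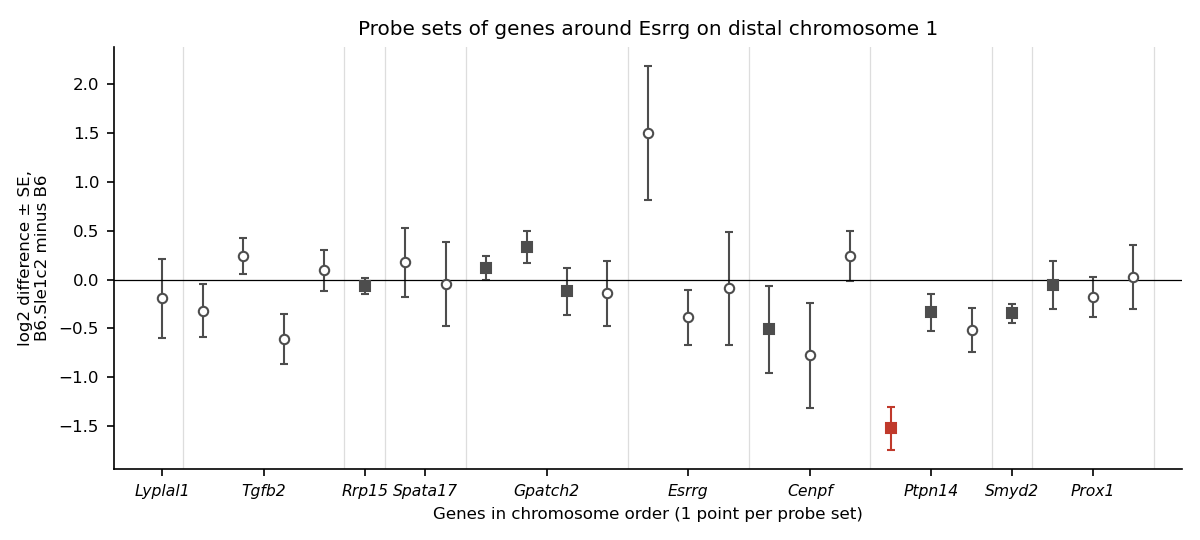
Log2 difference ± SE (B6.Sle1c2 minus B6) for 25 probe sets of 10 genes in chromosome order around Esrrg. Squares were above the background reference on all 10 arrays and open circles were not; the probe set in red, of Ptpn14, passed over the list alone.

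**Figure D4:**
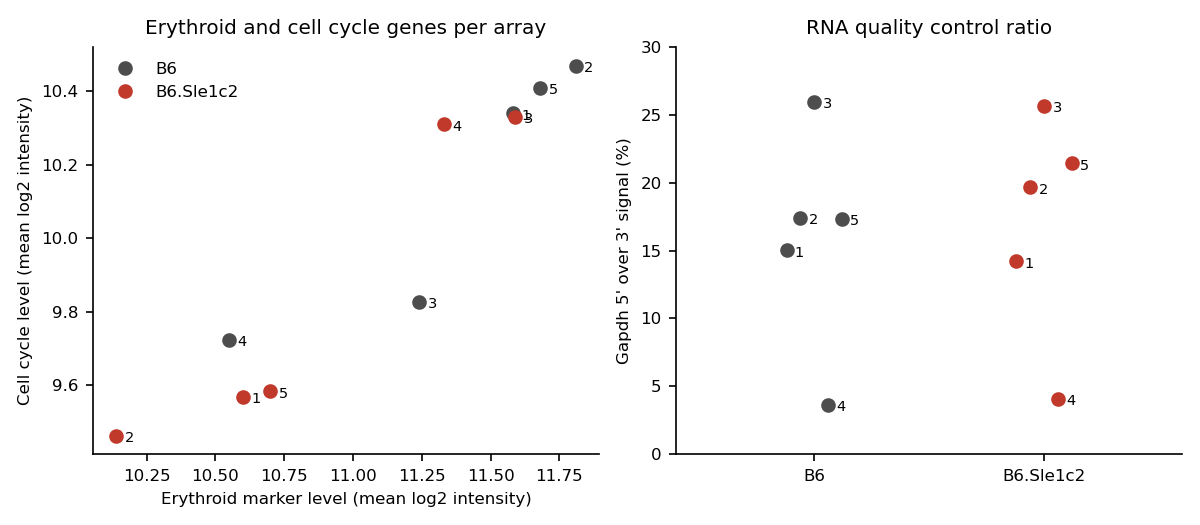
Left, the mean log2 intensity of erythroid markers against that of cell cycle genes on each array, numbered by replicate (r = 0.950). Right, the ratio of 5' to 3' Gapdh signal in percent, where replicate 4 of each strain lies at 3.62% and 4.04%.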

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

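Chosen only after results were seen were the test of the regulatory and activation lists without 2 arrays, both tests of the cell cycle list, the test of Ptpn14, the erythroid test of the called genes, the 4 tests of the regulatory and activation lists taken singly, the comparison of Foxp3 with other genes and the requirement that a covariate result hold without any 1 array. That requirement turned 2 of 8 such results from excluding an explanation to leaving it open. The tests of the erythroid level were prompted by another grouping of the arrays, described next.

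Chance was tested by dividing the 10 arrays into other groups of 5. Of 100 splits drawn, the strains' own included, 2 gave as many called probe sets as the strains (524, where the highest other split gave 920). For genes, 2 gave as many (378, highest other 545). Both counts were thus uncommon among groupings, under the limit of 5 in 100 set beforehand, but chance is not excluded, since 1 other split exceeded both. For the lists, 3 of 100 splits gave as many (15, highest other 19), so their number was uncommon too. This says little of any single list, since each of the 99 other splits shifted at least 1 list, with a median of 6, and 0 of the 15 passed with an estimated correlation. The split with more genes than the strains placed B6 replicates 1, 2 and 5 with B6.Sle1c2 replicates 3 and 4, and it points to a structure of the samples other than strain. It called 545 genes, 540 of them lower in the other 5 arrays, and shared 0 with the 378 called between strains. Its leading lists were cell cycle (median -0.87, 21 of 29 members called) and erythroid markers (median -0.95, 9 of 12).

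The cell cycle list was lower in B6.Sle1c2 cells with the preset correlation alone: its adjusted p was 0.626 with an estimated correlation and 0.364 with fry, and 0 of 29 members passed. A different share of erythroid cells could be neither shown nor excluded: with the erythroid marker level as a covariate the median went from -0.33 to 0.03 (a ratio of -0.092, from -0.24 to 0.079 without any 1 array), but the 2 levels followed each other within strains (r = 0.941), so this restates the relation that prompted the test. Loss of 5' signal in 2 arrays is argued against, since the median was -0.58 without them. With the 5' to 3' ratio as a covariate the difference stayed at 1.02 of its value (0.935 to 1.24). That result decides nothing, since the ratio was low on 1 array of each strain and could hardly move a strain difference. Whether the erythroid level differs by strain remains open, as its own exact permutation test gave p = 0.206, and why it was high after negative selection was not tested.

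Regulatory and activation genes were higher in B6.Sle1c2 cells with the preset correlation (adjusted p = 0.302 for each with an estimated one), and with the Foxp3 level as a covariate the median of the other regulatory genes fell to 0.137 of its value (0.121 to 0.262 without any 1 array). This leaves a larger share of Foxp3-expressing cells open, since Foxp3 did not overlap between strains and 59 of 783 other genes without overlap (7.54%) lowered the median as far. With the macrophage marker level as a covariate the 2 lists kept 0.815 of their median (0.609 to 0.913), a range that reaches below the bound of 0.8. Taken singly, without both arrays of low 5' signal the regulatory list kept 1.01 of its median (0.911 to 1.04 without 1 more array, camera adjusted p = 3.01e-10) and the activation list 0.865 (0.733 to 1.02, adjusted p = 4.047e-05), which argues against loss of 5' signal as the whole cause. With the macrophage level they kept 0.820 (0.508 to 0.877) and 0.687 (0.560 to 0.930) and still passed with the preset correlation. Macrophages as the whole cause are neither shown nor excluded, since the lowest values lie close to the bound of 0.5, set after the values were seen. A part played by macrophages, or by 5' loss in the activation list, stays open, as does the strain difference itself.

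For the called genes as a whole, the covariates changed the differences little. This cannot decide whether RNA quality, macrophage share or erythroid share took part. The 5' to 3' ratio was low on 1 array of each strain, so with all arrays that covariate could hardly move a strain difference. The called genes were also picked on these same arrays for differing by strain, 357 of them without overlap. Their median absolute difference kept 0.999 of its value with the 5' to 3' ratio as a covariate (0.995 to 1.04 without any 1 array) and 0.987 with the macrophage level (0.926 to 1.05), and 100% kept their direction in each case. With the erythroid level it kept 0.993 (0.932 to 1.01), and all 378 kept their direction. There 206 genes lost their call: their median absolute difference went from 0.74 to 0.70 while the median SE rose from 0.149 to 0.164, so smaller differences and wider errors both took part. For Ptpn14, a strain variant under the probes of 1 probe set can be neither excluded nor shown, since the other probe sets were lower with unadjusted limma p-values of 0.043 and 0.1003.

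Single arrays far from the other 4 of their strain were found in 20 of 280 groups of 5, where chance gives about 14. The measure is the gap to the nearest array over the whole range. B6 replicate 4, of low 5' signal, accounted for 8: lower ribosomal protein (0.855), fatty acid oxidation (0.825), glycolysis (0.796), mitochondrial biogenesis (0.784), oxidative phosphorylation (0.802), TCA cycle (0.754) and type I interferon (0.829) list means, and lower Rpl10a (0.825). B6.Sle1c2 replicate 4 had lower Rpl10a (0.717), Ubash3a (0.813) and Th2 list mean (0.871). B6.Sle1c2 replicate 5 had lower Slamf1 (0.723), Opa1 (0.860) and Prdm1 (0.792) and a higher heat shock mean (0.779). B6 replicate 2 had higher neutrophil (0.789) and gamma-delta T cell (0.769) means. The remaining values were Jcad in B6.Sle1c2 replicate 3 (0.718), Lyplal1 in B6.Sle1c2 replicate 2 (0.808) and a Spata17 probe set at the floor in B6 replicate 5 (0.727).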

How the results depend on the processing

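The counts of the strain comparison depended on the processing. Directions of the 378 called genes say little here, since 357 had no overlap between strains. Of 49 named called genes, 26 passed in every alternative that tested them, Il17a, Il10, Itgae, Gzmk and Eomes among them, and 0 reversed. The filter at the 50th percentile tested only 41 of the 49 and left out dim genes such as Ppp2r2c, Cyp17a1, Epha3 and Lmo1. Of the 28 genes that the naming rule took and that were not called, 8 passed in some alternative, and not all 28 are named in the text. Calls were lost most often for Ahr, Entpd1 and Zbtb16 (13 of 21 alternatives each), Pdzrn3 and Hspb1 (12), and Esm1, Cybb and Oas1a (11), followed by Lag3 and Itgb3 (10), Stab1 (10 of 20), Slamf1 and Ccl4 (9), Fcgr4 and Ifng (8), Mmp9 (7), Car1, Prdm1 and Ifi204 (6), Pklr (2), and Gdf3, Ptpn14 and Cd163l1 (1). Called probe sets, 524 in all arrays, fell to 297 and genes from 378 to 222 with no filter, where more are tested; array weights gave 1851 and 1126. Leaving out 1 array gave 182 to 749 probe sets and 159 to 517 genes, with 203 genes without B6 replicate 2, 241 without B6 replicate 3, 187 without B6 replicate 5, and 201, 159 and 161 without B6.Sle1c2 replicates 1, 2 and 3. Of the alternatives chosen after seeing the data, the 5' to 3' ratio as a covariate gave 1188 and 733, and the erythroid level 278 and 191; without both arrays of low 5' signal there were 479 and 335, and above the background reference 391 genes. With the replicate number as a block there were 103 probe sets and 207 genes; the numbers gave little sign of pairing, as correlations of same-numbered arrays ran from -0.12 to 0.37, 1 of 5 was over 0.1, and 2 of 10 arrays correlated best with their own number. The 15 shifted lists became 0 with an estimated correlation and 4 with fry; 9 of the 15 passed in every other alternative. Region probe sets that passed went from 1 to 2 with quantile normalisation, the offset, trend and robust fitting or array weights, and were 1 to 2 with 1 array left out. The odds ratio near Esrrg turned from 0.835 to 1.07 with up to 100 genes on either side (Fisher's exact p = 0.790), and the first component's exact permutation p went from 0.119 to 0.0238 over the 1000 most variable probe sets. Other reversals were of differences that did not pass with all arrays. With quantile normalisation they were 2 Prox1 probe sets (-0.0073 and 0.00052), ribosomal proteins (0.0067) and estrogen-related receptors (0.012), and with the mean of probe sets the latter (0.017) and heat shock (0.010). With array weights they were Prox1 (-0.00051) and Spata17 (0.040), and without both arrays of low 5' signal Prox1 (-0.18), Tgfb2 (-0.052) and CD8 markers (-0.037). Leaving out 1 array moved probe sets of Prox1 (-0.14 to 0.31 and -0.20 to 0.058), Gpatch2 (-0.33 to 0.017 and -0.35 to 0.12), Spata17 (-0.40 to 0.22), Tgfb2 (-0.081 to 0.18), Lyplal1 (-0.36 to 0.19) and Esrrg (-0.58 to 0.18) across 0. It did the same to the medians of ribosomal proteins (-0.063 to 0.015), estrogen-related receptors (-0.016 to 0.062), glycolysis (-0.00013 to 0.10), CD8 T cells (-0.13 to 0.15), mast cells (-0.076 to 0.25), stroma (-0.063 to 0.13), mitochondrial biogenesis (-0.077 to 0.0089) and oxidative phosphorylation (-0.12 to 0.0082). The causes of these changes were not tested. Signal over background limits Esrrg, whose probe sets gave no level above it in most arrays.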

Other observations

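Several called genes are known from cells other than T cells, and they did not all move one way. Fcgr4 and Cybb of myeloid cells were higher in B6.Sle1c2 cells, whereas Mmp9 of neutrophils, Itgb3 of platelets, Car1 of red cells, Stab1 of sinusoidal endothelium and Ighg3 of antibody-secreting cells were lower. Single genes do not stand for their cell type here: 8 of 10 neutrophil markers and 8 of 11 plasma cell markers were higher, and neither list passed.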
